A study of Homo sapiens with 30 samples.

How the data were processed

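RNA from cultured cell lines, labelled as breast cancer lines, was measured on 1-colour Agilent whole-genome arrays with 60-base probes labelled with Cy3, 30 arrays in all. The submitters describe amplification and labelling of 0.5 ug of RNA per sample with a low-input kit after column purification. Arrays came from 12 slides scanned on 6 days. The submitters' processing notes name Feature Extraction 9.1, whereas the headers give release 9.5 on 24 arrays and release 10.5 on 6, those labelled SKBR-3/ b1 and SK-EV-C4.

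Per the file headers, the processed signal of each spot is an intensity in arbitrary units, from which Feature Extraction had subtracted background and a spatial trend, with no scaling between arrays. The deposited table holds log2 values whose labels leave their scale, centring and direction unknown. Tested on the data, 24 of its 30 columns equalled the log2 processed signal of their own array, less that array's 75th percentile and each probe's median over the columns, to within an SD of 0.0236 log2 over 40516 probes. The 6 columns labelled MDA-MB-231 and MCF-7 matched no array within the tolerance of 0.1 log2 (SD 1.29 to 1.40). Column medians of that table ran from -0.40 to 0.99, so it served only as an alternative.

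Each array's processed signals were put on the log2 scale and its 75th percentile over non-control spots was subtracted. Of 41000 non-control probes, 23434 took their gene symbol through a RefSeq identifier, 5012 took the symbol in the files, and 12554 had none and stayed out of the gene tables. Spots of a probe were averaged, and each of 19170 genes was read from its probe with the highest mean normalized log2 signal over all 30 arrays. A gene entered a fit when its probe was well above background, as Feature Extraction calls it, on every array of at least 1 line in the fit, which left 17130 genes for the SKBR-3 family and 17696 for the panel of other lines. Probe positions are those in the files (human build hg17). No genome sequence was held, so the part of a gene under a probe was not looked up.

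Fits used limma 3.58.1 (statmod 1.5.0, R 4.3.3) with lmFit and eBayes. The 15 arrays of SKBR-3 and the 4 lines named as its derivatives made 1 fit with 10 residual degrees of freedom, so that all 7 comparisons shared an estimate of the spread. All 30 arrays made a fit for the other lines against SKBR-3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with a change of at least 2-fold, two-sided, adjusted within each comparison. Fold changes, SE and adjusted p below come from these fits, and errors after ± are SD over 3 arrays. The difference between the changes in 2 comparisons was tested as a contrast of 4 lines in the family fit, and a gene counted as changed in every pairing of 4 lines when it was called the same way in all 4 comparisons. Replicate numbers were not taken as pairs, because no comparison had correlated array differences in all 3 numbered pairs; a replicate block was an alternative.

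Where every array of one group was above background and none of the other was, the fold is given as a lower bound. The dim group was then set, on each array, to the higher of the lowest signal among probes well above background and the probe's own signal, on the normalized log2 scale. Saturated spots bound a fold in the same way, and so do lines with only some arrays above background, whose number is given.

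Gene groups were 30 lists: integrin subunits, focal adhesion and actin linkers, extracellular matrix, N-glycan assembly and processing, HER receptors and ligands, the 17q12 HER2 amplicon, trastuzumab response, epithelial junction and keratin, mesenchymal, luminal and estrogen receptor, basal epithelial, melanocytic, fibroblast, leukocyte, interferon-stimulated, antigen presentation, NF-kB targets and cytokines, immediate early, MAPK output, proliferation, hypoxia and glycolysis, sterol and fatty acid synthesis, unfolded protein and amino acid stress, heat shock, p53 targets, invasion proteases and inhibitors, stem cell associated, drug efflux, cytosolic ribosome, and oxidative phosphorylation. For 5 list symbols the array had no probe. Lists were tested with camera over 17088 genes without missing values, with a preset correlation of 0.01, and again with the correlation estimated from the data, adjusted over the 30 lists. A list's median covers all its measured members. The lists, comparisons, thresholds and the rule for named genes were fixed before the data were examined.

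That rule took, per comparison, the 6 called genes with the largest rise and the 6 with the largest fall among unsaturated genes above background on all arrays of both lines, with non-overlapping arrays and a proper symbol. It added the 3 brightest genes on in one line and off in the other for each direction, ITGB1 and ERBB2, and from each list up to 4 members with the smallest adjusted p besides members needed to describe it. Comparisons after the first 2 print the first 3 rises and falls and 1 gene on or off. For the other lines the rule took up to 4 genes per list by the range of line means, and for genes changed in every pairing the 8 of each direction with the largest smallest fitted fold. Those whose smallest fold rests on a line not above background are given by their bound, unranked.

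The design text of the series names a t-test with Bonferroni correction and an ANOVA, with "p-value of >0.05" and ">0.02" as thresholds, read here as under. Both were run as alternatives, the first at 0.02 and 1.5-fold on arrays of SK-B1-C1 and SKBR-3/ EV, and the ANOVA over SK-B1-C1, SKBR-3/ b1 and SK-EV-C4 at an adjusted p under 0.05 and 2-fold. Other alternatives were quantile scaling, median centring, normexp background correction with an offset of 50, the deposited table, the mean of all probes, no filter, a stricter filter, other fold minimums, slide or replicate as a block, array weights, groups fitted alone, and each array left out. Scan day could not be fitted beside the lines, since each family line was scanned on 1 day.

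The pipeline was tested on simulated data in which 50 genes each were changed between arrays standing for SK-B1-C1 and SKBR-3/ EV. It called 1 of those changed 1.5-fold, 15 at 2-fold, 39 at 4-fold and 43 at 8-fold, with 9 unchanged genes called among 17088. The pass mark set for the 4-fold genes was missed, and the analysis went on without it. The 1 list shifted 2-fold was called, and 0 lists were called where none was shifted. Arrays per line, 3, limit the precision of every value. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.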

Results

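Messenger RNA was measured in 10 human cell lines, all labelled as breast cancer lines by the submitters, each on 3 arrays, 30 arrays in all. SKBR-3 is an ERBB2-amplified line. The labels give 4 further lines whose names derive from it, SKBR-3/ EV, SK-EV-C4, SKBR-3/ b1 and SK-B1-C1. EV and b1 are not spelled out, though the series concerns a beta integrin and resistance to HER2-directed therapy. The remaining lines were MDA-MB-231 and MDA-MB-468, which lack hormone receptors and ERBB2 amplification, the estrogen receptor-positive MCF-7 and ZR75-1, and MDA-MB-435. Line names below stand for arrays so labelled. Whether the 3 arrays of a line came from separate cultures is not stated. The p-values measure only spread between replicate arrays, pooled over all lines of a fit. SKBR-3, whose replicates correlated least (r 0.934 to 0.980), enters that pool. The spread used for a comparison can thus be wider or narrower than that of its own lines.

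Signal above background differed between lines. The 75th percentile of the processed signal was 1021 to 1287 on the SKBR-3/ EV arrays, 929 to 1343 for SK-B1-C1, 430 to 558 for SKBR-3/ b1 and 383 to 518 for SK-EV-C4. It was 87.8 to 246 for SKBR-3, 264 to 1307 for MDA-MB-231, 475 to 919 for MDA-MB-435, 954 to 1231 for MDA-MB-468, 447 to 639 for MCF-7 and 245 to 618 for ZR75-1. Between 37.8% and 55.0% of probes were well above background on the SKBR-3 arrays, against 60.3% to 82.1% on the other 27. SKBR-3/ EV and SK-B1-C1 were scanned on 1 day together with SKBR-3, and SKBR-3/ b1 and SK-EV-C4 on another. No slide held lines of both days, so that a difference between lines of different days cannot be told apart from the day. Replicate arrays correlated across genes at r from 0.934 to 0.996.

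ITGB1, the beta-1 integrin subunit after which the b1 lines appear to be named, was not uniformly higher in them. Read from a probe on chromosome 10 (33229449 to 33229508, hg17), its normalized log2 level was 4.78 ± 0.02 in SKBR-3/ EV, 6.07 ± 0.03 in SK-B1-C1, 4.46 ± 0.06 in SKBR-3/ b1, 6.39 ± 0.02 in SK-EV-C4 and 5.19 ± 0.31 in SKBR-3 (SD, n = 3). In the other lines it was 5.87 ± 0.52 in MDA-MB-231, where 2 of 3 arrays were saturated, 5.76 ± 0.08 in MDA-MB-435, 4.44 ± 0.10 in MDA-MB-468, 4.603 ± 0.56 in MCF-7 and 4.91 ± 0.14 in ZR75-1. ITGB1 was 2.45-fold higher in SK-B1-C1 than in SKBR-3/ EV (1.29 log2, SE 0.13, adjusted p = 2.79e-06), and its other 2 probes on chromosome 10 gave 1.47 and 1.54. A further probe named ITGB1 in the files, which place it on chromosome 8, was not taken as evidence on ITGB1. In SKBR-3/ b1 it was 3.83-fold lower than in SK-EV-C4 (-1.94 log2, SE 0.13, adjusted p = 1.23e-07). The other chromosome 10 probes gave -0.49 and -0.68 there, neither called. The mean of all 3 gave -1.035 (adjusted p = 0.00401), just past the 2-fold minimum. Against SKBR-3/ EV, the SKBR-3/ b1 level differed by -0.33 log2 (adjusted p = 0.0382), also under 2-fold, while the other chromosome 10 probes gave 0.33 and 0.21, so that no direction held for this pair. Median centring of the arrays took the first probe to -1.41, past the minimum. On the other probes SK-B1-C1 stood above SK-EV-C4 (3.25 against 2.597, and 1.74 against 1.09).

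ERBB2, the HER2 receptor gene on chromosome 17 (probe at 35138355 to 35138414), stood at 9.71 ± 0.76 in SKBR-3, 6.86 ± 0.18 in SKBR-3/ EV, 7.103 ± 0.01 in SKBR-3/ b1, 4.18 ± 0.03 in SK-EV-C4 and 1.52 ± 0.02 in SK-B1-C1. MDA-MB-435 was at 1.02, MDA-MB-468 at 2.85, MDA-MB-231 at 3.12, MCF-7 at 3.22 and ZR75-1 at 4.66. This probe was saturated on all 3 SKBR-3/ EV arrays, so that SK-B1-C1 was at least 40.6-fold lower (adjusted p = 3.82e-09). A second, unsaturated ERBB2 probe (35120176 to 35120235) fell by 6.06 log2 between them (66.8-fold, SE 0.345, adjusted p = 1.11e-08).

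**Figure D1:**
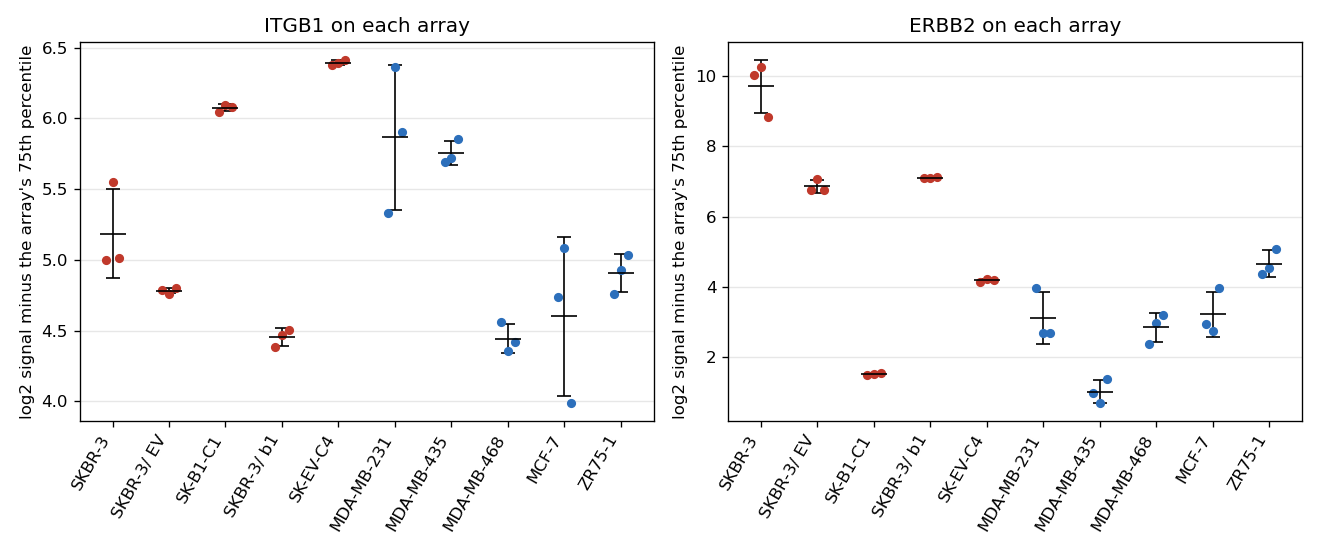
Normalized log2 signal (signal minus the array's 75th percentile) of ITGB1 (left) and ERBB2 (right) on each array, by line; points are arrays, the long bar is the mean and the error bar the SD of 3 arrays, red for SKBR-3 and the lines named after it. SK-B1-C1 had the lowest ERBB2 mean of the red lines (1.52), and SK-EV-C4 the highest ITGB1 mean on the probe shown (6.39), though not on the other chromosome 10 probes.

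The first comparison set SK-B1-C1 against SKBR-3/ EV, the pair that the design text of the series singles out. In SK-B1-C1 22 of 24 epithelial genes were lower, and 19 of 25 mesenchymal and 20 of 31 matrix genes higher. The calls of these lists were lost with an estimated correlation (adjusted p = 0.0702, 0.075 and 0.075). VIM, the intermediate filament of mesenchymal cells, was at least 13.3 log2 higher (6.76 against -6.57, above background on 2 of 3 SKBR-3/ EV arrays and saturated on 2 SK-B1-C1 arrays). EPCAM, an epithelial adhesion molecule, was 608-fold lower (-9.25 log2, SE 0.137, adjusted p = 7.85e-14), and MAL2, which works in apical transport, went from clear signal in SKBR-3/ EV to none above background, at least 8081-fold lower. GRB7 and other neighbours of ERBB2 fell with it. In all, 7059 of 17130 genes were called, 2920 higher and 4139 lower, of which 4305 were above background in both lines (2127 higher, 2178 lower). Arrays of the lines did not overlap for 79.9% of genes, where chance gives 10%.

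The largest rises among unsaturated genes above background on all 6 arrays were MSN, moesin, which links actin to the membrane (1939-fold, 10.9 log2, SE 0.18, adjusted p = 1.61e-13), SPARC, a matricellular protein (1114-fold, SE 0.207), DPYSL3 (969-fold), SERPINE2, a protease inhibitor (753-fold), STC2 (726-fold) and BEX3 (645-fold). Among the falls were INHBB, an activin subunit (1117-fold, SE 0.152), the imprinted RNA H19 (1000-fold, SE 1.05), GSDMB, a gasdermin beside ERBB2 (835-fold, SE 0.13), the cancer-testis antigens MAGEA2B (721-fold) and MAGEA12 (607-fold), and EPCAM. Genes on in SK-B1-C1 and off in SKBR-3/ EV were led by AKR1C1, a ketosteroid reductase (at least 7075-fold), the nuclear receptor NR2F1 (at least 3571-fold) and GNG11 (at least 2643-fold). S100A14 (at least 5568-fold) and CKMT1B (at least 2462-fold) were off in SK-B1-C1.

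Of 24 epithelial junction and keratin genes, 22 fell and 0 rose (median -8.68 log2, or -8.06 with genes at their bound, adjusted p = 1.67e-13). With an estimated correlation the adjusted p = 0.0702. ESRP2, an epithelial splicing regulator, was 249-fold lower (SE 0.113), and the tight-junction gene CLDN3 fell by at least 10.4 log2, with 1 of 3 SK-B1-C1 arrays above background. CDH1, E-cadherin, was above background on no array of either line. In the mesenchymal list 19 of 25 rose and 3 fell (median 5.90, adjusted p = 1.12e-07, and adjusted p = 0.075 with an estimated correlation). AXL, a receptor kinase, was 333-fold higher (SE 0.221) and LOX, which crosslinks collagen, at least 369-fold. Extracellular matrix genes rose in 20 of 31 cases and fell in 5 (median 3.56, adjusted p = 1.08e-06, and adjusted p = 0.075 with an estimated correlation). COL6A1 (at least 647-fold, 1 SK-B1-C1 array saturated) and COL6A3 (543-fold) encode collagen VI chains, and LAMA4, a laminin chain, was at least 1491-fold higher. Among 9 fibroblast markers 5 rose and 2 fell (median 1.78, adjusted p = 0.0317, and adjusted p = 0.118 with an estimated correlation), with PDGFRB at least 533-fold, FAP at least 130-fold and THY1 78.8-fold higher. That call was lost when the SKBR-3 arrays left the fit.

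In the 17q12 HER2 amplicon list 15 of 16 genes fell and 0 rose (median -3.34, or -2.98 at the bounds, adjusted p = 2.28e-06). The adjusted p = 0.118 with an estimated correlation. MIEN1 fell by at least 3.46 log2, with 2 of 3 SKBR-3/ EV arrays saturated, MED1 fell by 3.25 log2, CASC3 fell by 2.71, and GRB7, an adaptor that binds ERBB2, fell as well, with 2 of 3 SK-B1-C1 arrays above background. PSMB3, the first of the list along the chromosome, differed by 0.75 and was not called. HER receptors and ligands went both ways, 3 rising and 9 falling of 15 (median -1.59, or -0.60 at the bounds, adjusted p = 0.144). ERBB3 was at least 173-fold, AREG at least 24.9-fold and BTC at least 4.76-fold lower, while NRG1, a ligand of ERBB3, was at least 434-fold higher.

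**Figure D2:**
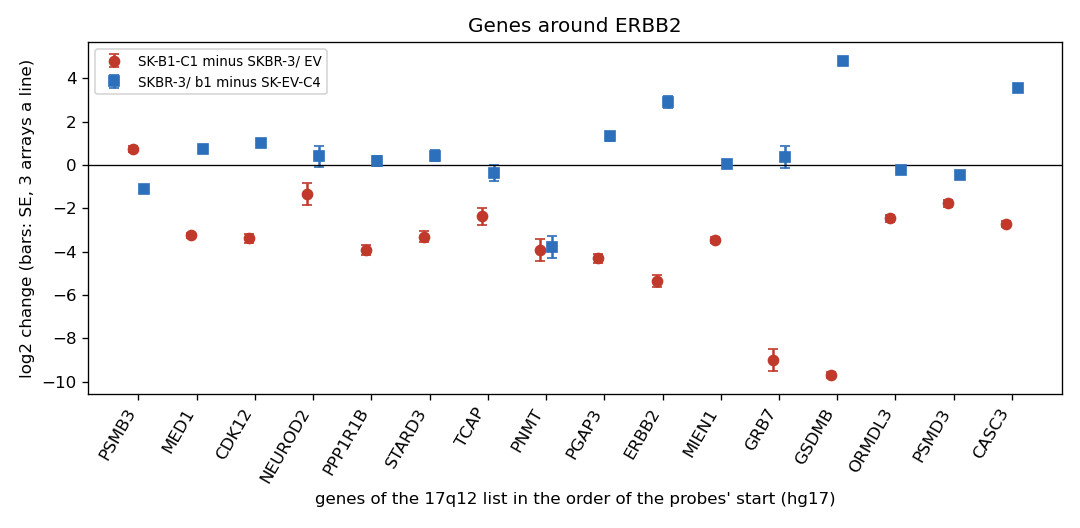
Log2 change (vertical axis) of each gene of the 17q12 list, ordered along chromosome 17 by probe start, for SK-B1-C1 minus SKBR-3/ EV (red circles) and SKBR-3/ b1 minus SK-EV-C4 (blue squares); bars are SE, 3 arrays a line. All genes but PSMB3 lay below 0 in the first comparison, from -1.36 (NEUROD2) to -9.71 (GSDMB), while in the second ERBB2 was at 2.92 and PNMT at -3.80.

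Interferon-stimulated genes rose in 19 of 30 cases and fell in 2 (median 2.22, adjusted p = 1.18e-07, and adjusted p = 0.075 with an estimated correlation). BST2, tetherin, was 144-fold higher (SE 0.114), the antiviral GTPase MX2 35.5-fold and IFI44L 30.8-fold. Of 17 antigen presentation genes 7 rose and 1 fell (median 0.48, adjusted p = 0.019, and adjusted p = 0.186 with an estimated correlation), among them the immunoproteasome subunit PSMB9 (15.5-fold) and HLA-F (63.5-fold). Invasion proteases and inhibitors rose in 13 of 24 cases and fell in 7 (median 1.85, adjusted p = 0.019, and adjusted p = 0.575 with an estimated correlation). The collagenase MMP1 was 40.8-fold higher, and the epithelial membrane protease ST14 582-fold lower. Focal adhesion and actin linkers rose in 10 of 30 cases and fell in 3 (median 0.70, adjusted p = 0.048, and adjusted p = 0.337 with an estimated correlation). LPXN rose by 4.87 log2, FERMT1, a kindlin, by 4.17 and TNS3 by 2.45, and NEDD9 fell by at least 5.63 with 1 of 3 SK-B1-C1 arrays above background. This call was lost without SK-B1-C1 replicate 1, SK-B1-C1 replicate 3 or SKBR-3/ EV replicate 2, and, like the antigen presentation call, with the mean of all probes; it was also lost without a filter on dim genes. Oxidative phosphorylation shifted down (median -0.55, adjusted p = 0.0186, and adjusted p = 0.662 with an estimated correlation), though only 4 of 28 members were called, all lower, COXFA4 and NDUFV1 among them at -1.33 and -1.15. Quantile scaling ended that call.

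The other 19 lists were not called as groups. Integrin subunits held 10 rises and 4 falls in 25 (median 1.04, adjusted p = 0.0704): ITGA6 was 126-fold and ITGA3 7.47-fold higher, partners of beta-1 in laminin receptors, and ITGB4 was 36.5-fold lower. N-glycan assembly and processing held 5 rises and 10 falls in 46 (median -0.28, adjusted p = 0.476), with falls of 3.25 log2 for the sialyltransferase ST6GAL1 and 1.62 for B4GALT1. Rises and falls were 9 and 6 of 23 for trastuzumab response (adjusted p = 0.308), 4 and 11 of 19 for luminal and estrogen receptor genes (0.0954), 5 and 9 of 18 for basal epithelial (0.41), 5 and 4 of 15 for melanocytic (0.392) and 2 and 3 of 10 for leukocyte genes (0.792). Members included the luminal factors FOXA1, which fell by 3.31 log2, and TFF3, which fell by 6.37, the basal gene TRIM29, at least 227-fold lower, and the melanocytic gene TYRP1, at least 43.1-fold higher. NF-kB targets and cytokines had 6 rises and 11 falls in 27 (0.641), immediate early genes 1 and 9 in 18 (0.193), MAPK output 8 and 1 in 18 (0.0578), proliferation 5 and 1 in 35 (0.0672), hypoxia and glycolysis 8 and 3 in 22 (0.308), and sterol and fatty acid synthesis 5 and 5 in 25 (0.737). S100A8 was at least 2141-fold lower, FOSL1, a component of AP-1, rose by 6.84 log2, and the desaturases FADS1 and FADS2 rose by 8.12 and 6.74 while FASN fell by 3.56. Counts were 3 and 6 of 22 for unfolded protein and amino acid stress (0.792), 2 and 1 of 16 for heat shock (0.641), 5 and 3 of 16 for p53 targets (0.641), 7 and 8 of 19 for stem cell associated genes (0.737), 4 and 4 of 10 for drug efflux (0.626) and 0 and 0 of 29 for the cytosolic ribosome (0.792). For heat shock the median (-0.02) and mean were below 0 and the test pointed up. In the last groups CD24, a surface sialoglycoprotein, was 57.7-fold lower, and GSTP1, a glutathione transferase saturated on all SK-B1-C1 arrays, was at least 1101-fold higher. Adjusted over the list alone, counts moved only for integrin subunits (11 rises, 4 falls) and invasion proteases (14 and 7).

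**Figure D3:**
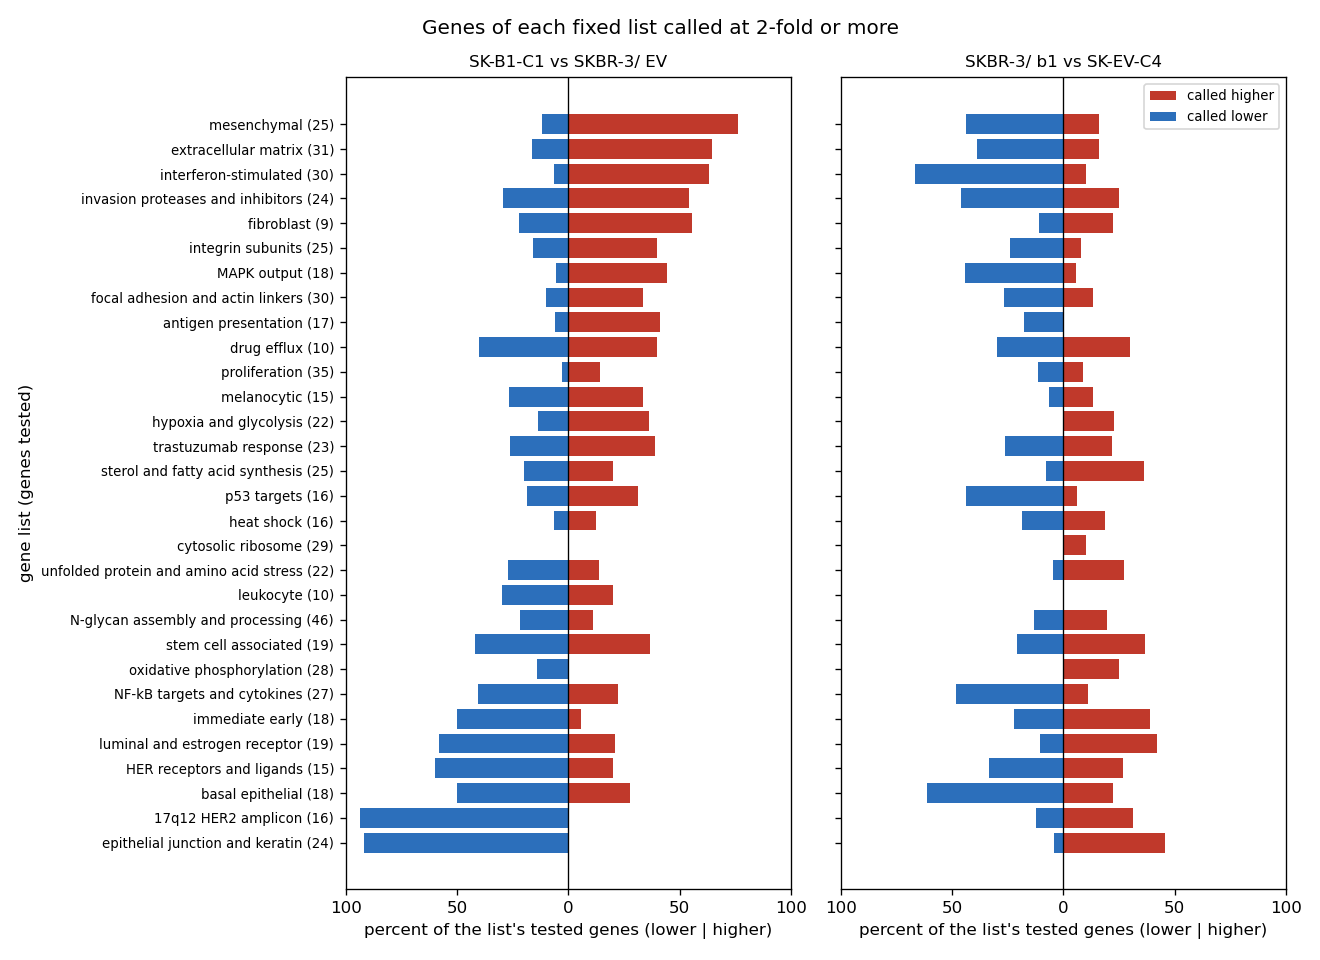
Percent of each list's tested genes (number in parentheses) called higher (red, right of 0) or lower (blue, left of 0) at 2-fold or more, for SK-B1-C1 vs SKBR-3/ EV and SKBR-3/ b1 vs SK-EV-C4. In the first, 22 of 24 epithelial genes and 15 of 16 amplicon genes were lower, and 19 of 25 mesenchymal genes were higher.

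A single slide held all 3 SKBR-3/ EV arrays and 1 SK-B1-C1 array. Within it ERBB2 differed by -5.36 log2 or lower, ITGB1 by 1.27, VIM by at least 13.1, the epithelial list median by -8.24, the amplicon by -3.33, the mesenchymal list by 5.74 and the interferon list by 2.18. A fit with slide as a fixed block, which rests on these within-slide differences, called 5689 genes and 9 lists, and no longer the focal adhesion list (0.74 within the slide).

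SKBR-3/ b1 against SK-EV-C4 pairs the remaining b1-named and EV-named lines. In SKBR-3/ b1 20 of 30 interferon-stimulated genes were lower, as were MSN and the laminin-receptor subunit ITGA6, and 9 of 25 genes of sterol and fatty acid synthesis and 8 of 19 luminal genes were higher. With an estimated correlation the calls of these 3 lists were lost (adjusted p = 0.183, 0.528 and 0.515). OASL, an interferon-induced protein, was 447-fold lower (-8.81 log2, SE 0.113, adjusted p = 2.85e-13), and ITGA6 439-fold lower (SE 0.367). ERBB2 was 7.57-fold higher (2.92 log2, adjusted p = 2.13e-06), and its unsaturated probe gave 7.89-fold. CDH1 was above background on all 3 SK-EV-C4 arrays (2.89 ± 0.09) and on none of SKBR-3/ b1, at least 569-fold lower. There were 4636 called genes, 2200 higher and 2436 lower, 3730 of them above background in both lines (1799 higher, 1931 lower). Arrays did not overlap for 73.5% of genes, against 10% by chance.

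Among unsaturated genes above background on all arrays of both lines, the largest rises were H19 (1243-fold, SE 1.05, adjusted p = 4.44e-06) and the cancer-testis antigen CTAG1A (893-fold, SE 0.181). Next came FBP1, a gluconeogenic enzyme (642-fold), the growth factor BMP7 (454-fold), EDN2, an endothelin (407-fold), and the chemokine CX3CL1 (149-fold). Among the falls of such genes MSN was 492-fold lower (SE 0.18), followed after OASL and ITGA6 by DSE (319-fold), CMTM3 (270-fold) and SUN3 (211-fold). IGFBP5 (at least 2805-fold), OLFM4 (at least 1736-fold) and VTCN1, an immune checkpoint ligand (at least 757-fold), were on only in SKBR-3/ b1 of this pair. G0S2, a lipase inhibitor (at least 2723-fold), BARX1 (at least 684-fold) and IL13RA2 (at least 604-fold) were on only in SK-EV-C4 of the pair.

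Interferon-stimulated genes fell in 20 of 30 cases and rose in 3 (median -1.86 log2, adjusted p = 1.18e-06, and adjusted p = 0.183 with an estimated correlation). BST2 was 75.6-fold and ISG15, a ubiquitin-like modifier, 29.8-fold lower. NF-kB targets and cytokines fell in 13 of 27 cases and rose in 3 (median -1.101, or -0.83 at the bounds, adjusted p = 0.0164, and adjusted p = 0.27 with an estimated correlation). IL1A was at least 120-fold lower, IL6 fell by 3.36 log2 and TNFAIP3, a feedback inhibitor, by 3.89, whereas S100A8 rose by 4.603. Of 18 MAPK output genes 8 fell and 1 rose (median -1.21, or -1.13 at the bounds, adjusted p = 0.00154, and adjusted p = 0.122 with an estimated correlation), with the ETS factors ETV4 down by 4.80 and ETV5 at least 34.2-fold lower. The gene that rose, SPRY1, a feedback inhibitor of the pathway, was at least 16.8-fold higher.

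Epithelial junction and keratin genes rose in 11 of 24 cases and fell in 1, CDH1 (median 1.11, adjusted p = 0.00516, and adjusted p = 0.515 with an estimated correlation). MAL2 rose by 2.59 log2 and ESRP2 by 2.09. Luminal and estrogen receptor genes rose in 8 of 19 cases and fell in 2 (median 0.45, adjusted p = 0.0239, and adjusted p = 0.515 with an estimated correlation), with FOXA1 16.1-fold higher, CA12 up 5.27 log2 and MYB up 3.99. Their call was lost without the SKBR-3 arrays. Sterol and fatty acid synthesis rose in 9 of 25 cases and fell in 2 (median 0.69, adjusted p = 0.0276, and adjusted p = 0.528 with an estimated correlation), led by the sterol demethylase CYP51A1 (3.19 log2), the desaturase SCD (3.08), ACLY (2.89) and FASN (2.81), and that call was lost when all probes of a gene were averaged. Oxidative phosphorylation rose in 7 of 28 cases and fell in 0 (median 0.48, adjusted p = 0.0116, and adjusted p = 0.727 with an estimated correlation), COX7C by 1.89 and COXFA4 by 1.68.

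The remaining 23 lists were not called here, and many held members that moved both ways. Basal epithelial genes had 4 rises and 11 falls in 18 (median -1.99, adjusted p = 0.148), with KRT5 down by 4.66 log2 and LAMC2 (-5.69). Extracellular matrix genes had 5 rises and 12 falls in 31 (adjusted p = 0.0529), with COL6A1 down by 5.63, SPARC (-6.15) and LAMA3 (-7.12). In the amplicon list 5 rose and 2 fell of 16 (adjusted p = 0.192): GSDMB rose by 4.79 and CASC3 by 3.53, and PNMT and PSMB3 fell by 3.80 and 1.12. Integrin subunits had 2 rises and 6 falls in 25 (adjusted p = 0.159), among them ITGA2 (-4.02) and ITGA3 (-3.69), and N-glycan genes 9 rises and 6 falls in 46 (adjusted p = 0.276), ST6GAL1 rising by 3.60. HBEGF, an EGFR ligand, fell by 4.54 and EGFR rose by 1.72. GSTP1 fell by 7.43, and IRS2, an insulin receptor substrate, by 4.72. Adjusted over the list alone, counts moved for integrin subunits (1 rise, 6 falls), antigen presentation (0 and 4) and hypoxia (5 and 1). For drug efflux the median (0.02) and the test pointed up and the mean down. Another slide held all SK-EV-C4 arrays and 1 SKBR-3/ b1 array, and within it ERBB2 differed by 2.91, ITGB1 by -2.01, the interferon list median by -1.91, the NF-kB list by -1.61, MAPK output by -0.94, the epithelial list by 1.03, the luminal list by 0.72, the sterol list by 0.69 and oxidative phosphorylation by 0.42. A fit with slide as a fixed block called 4031 genes and 8 lists, the extracellular matrix list (-0.36 within the slide) being added.

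These comparisons share no array, and their gene changes ran against each other (Pearson r = -0.481, Spearman rho = -0.451 across genes, which are not independent replicates). Of 2896 genes called in both, 2504 (86.5%) went opposite ways: 1287 were higher in SK-B1-C1 and lower in SKBR-3/ b1, where 415 would be if the calls were independent, and 1217 the reverse (532). Both higher were 134 (375) and both lower 258 (589). MSN, ITGA6, SPARC, BST2 and AXL rose in the first and fell in the second, and H19, GSDMB, ESRP2, FOXA1 and CD24 did the reverse. EPCAM fell in the first and was not called in the second. A test of the difference between the changes called 9077 genes, 4022 positive and 5055 negative (3566 and 3168 with normexp correction). Among them, with all 12 arrays above background and none saturated, MSN differed by 19.9 log2, SPARC by 16.3, ITGA6 by 15.8, BST2 by 13.4, AXL by 12.3 and H19 by -20.2.

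**Figure D4:**
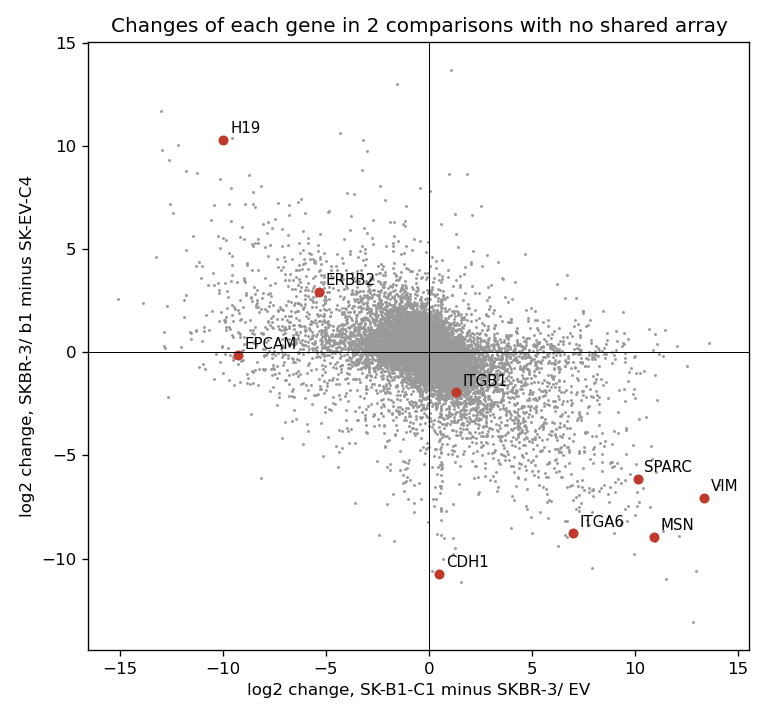
Log2 change of each gene in SK-B1-C1 minus SKBR-3/ EV (horizontal axis) against SKBR-3/ b1 minus SK-EV-C4 (vertical axis); each point is a gene of the family fit, and red points are labelled genes. MSN and ITGA6 lie at the lower right and H19 at the upper left (r = -0.481).

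Across all 4 pairings of a b1-named with an EV-named line, 122 genes changed the same way, 51 higher and 71 lower, 0.712% of those tested. The split depended on scaling, with 24 higher and 120 lower under median centring and 35 and 116 under quantile scaling. The higher ones were led by PTGER3, a prostaglandin receptor (smallest fold 7.96, on no SKBR-3/ EV array above background), IGFBP3 (7.96), CPEB1 (6.45), TNFRSF14 (4.02), IRS1 (3.93, above background on 2 of 3 SK-EV-C4 arrays) and COL5A2 (3.80). The thrombin receptor F2R and the gelatinase MMP2 were above background on 2 of 3 SKBR-3/ b1 arrays and on none of either EV-named line, and their smallest bounds were only at least 1.50-fold and 1.14-fold. With normexp background correction F2R (-0.47) and MMP2 (-0.54) reversed between SKBR-3/ b1 and SK-EV-C4, and PTGER3 reversed to -0.07 between SK-B1-C1 and SK-EV-C4 with the mean of all probes. Lower ones included IFNLR1, an interferon lambda receptor chain (7.18), CRIP1 (6.99), RPP25 (6.71), ARSI (6.29, off in SK-B1-C1), COL9A3 (5.27) and ID4 (4.70). The chemokine CXCL11 and CUZD1 were above background on no array of either b1-named line, so that they were at least 1.36-fold and 2.22-fold lower in every pairing, and with normexp correction they reversed between SKBR-3/ b1 and SKBR-3/ EV (0.66 and 0.37). With bounds in place of fitted folds, 107 of the 122 kept 2-fold in every pairing. Pairing the 4 lines by scan day instead gave 6132 genes, and the remaining pairing 1585, so that the names gave the fewest.

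Among SK-B1-C1, SKBR-3/ b1 and SK-EV-C4, the 3 lines that the design text compares pairwise, 13779 genes differed by limma's F-test with a change of at least 2-fold. SK-B1-C1 against SK-EV-C4, lines scanned on different days, gave 11440 called genes, 5136 higher and 6304 lower. Among the 7199 above background in both the balance turned, with 4714 higher and 2485 lower, as it did under median centring (65.1% higher), and 93.0% of genes had non-overlapping arrays (10% by chance). LYPD1 rose by 8.65 log2, NNMT, a nicotinamide methyltransferase, by 8.51 and AKR1B10, an aldose reductase relative, by 8.47, while SPINT2, a protease inhibitor of epithelia, fell by 9.55, LYPD3 (-9.30) and MOP-1 (-8.94). GNG11 was at least 1543-fold higher and TACSTD2, an EPCAM relative, at least 6912-fold lower. ERBB2 was 6.34-fold lower (adjusted p = 1.52e-06), and ITGB1 differed by -0.32 (adjusted p = 0.0402), not called, while its other chromosome 10 probes both gave 0.65. Epithelial genes fell in 23 of 24 cases and rose in 0 (median -6.73, or -6.18 at the bounds, adjusted p = 1.98e-09, and adjusted p = 0.21 with an estimated correlation), EPCAM (-8.49). Amplicon genes fell in 11 of 16 and rose in 2 (median -2.66, adjusted p = 0.00693, and adjusted p = 0.493 with an estimated correlation), GSDMB (-3.04). Basal epithelial genes fell in 13 of 18 and rose in 2 (median -3.48, or -2.47 at the bounds, adjusted p = 0.00693, and adjusted p = 0.467 with an estimated correlation), KRT5 by at least 402-fold. NF-kB targets fell in 18 of 27 and rose in 3 (median -2.83, or -2.47 at the bounds, adjusted p = 0.00544, and adjusted p = 0.38 with an estimated correlation), LCN2 by at least 219-fold.

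Higher in SK-B1-C1 than in SK-EV-C4 were 18 of 25 mesenchymal genes, with 3 lower (median 2.83, adjusted p = 0.00457, and adjusted p = 0.467 with an estimated correlation), including FBN1, fibrillin (6.05 log2), and S100A4 (5.09), but SERPINE1 fell by 4.54. Proliferation genes rose in 27 of 35 cases and fell in 0 (median 1.36, adjusted p = 0.000614, and adjusted p = 0.712 with an estimated correlation), the kinesin KIF20A by 4.67 and the helicase subunit MCM5 by 2.70. Rises and falls were 13 and 2 of 22 for hypoxia and glycolysis (median 1.48, adjusted p = 0.0181, and adjusted p = 0.467 with an estimated correlation), P4HA1 rising by 3.23 and CA9 falling by 3.53. They were 13 and 2 of 25 for sterol and fatty acid synthesis (median 1.00, adjusted p = 0.00544, and adjusted p = 0.467 with an estimated correlation), SCD rising by 3.88. The unfolded protein list had 9 and 2 of 22 (median 1.28, adjusted p = 0.0385, and adjusted p = 0.712 with an estimated correlation), PHGDH of serine synthesis rising by 4.298, the cytosolic ribosome 17 and 0 of 29 (median 1.08, adjusted p = 0.00175, and adjusted p = 0.712 with an estimated correlation), and oxidative phosphorylation 17 and 0 of 28 (median 1.23, adjusted p = 0.000127, and adjusted p = 0.493 with an estimated correlation), NDUFA9 rising by 3.08. Quantile scaling ended the ribosome and unfolded protein calls, median centring the latter, and the mean of all probes the hypoxia call. For immediate early genes the median (0.38) and test pointed up and the mean (-0.11) down.

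SK-B1-C1 against SKBR-3/ b1, also scanned on different days, gave 11740 called genes, 5333 higher and 6407 lower. Of these, 7346 were above background in both and leaned the other way (4790 higher, 2556 lower), as did all under median centring (64.1% higher), with 93.0% of genes non-overlapping against 10% by chance. DKK3 and COL1A2 rose by 10.6 log2 and MSN by 9.67, and H19 fell by 10.9, the keratin KRT19 (-10.6) and SPINT2 (-9.48). VIM was at least 8312-fold higher and MAL2 at least 6212-fold lower. ITGB1 rose by 1.62 (adjusted p = 1.68e-07), and ERBB2 was 48.0-fold lower (adjusted p = 1.6e-09). Epithelial genes fell in 23 of 24 cases and rose in 0 (median -7.90, or -7.58 at the bounds, adjusted p = 2.2e-09, and adjusted p = 0.213 with an estimated correlation), and amplicon genes fell in 14 of 16 and rose in 1, PSMB3 (median -2.82, or -2.45 at the bounds, adjusted p = 0.00148, and adjusted p = 0.475 with an estimated correlation). Mesenchymal genes rose in 20 of 25 and fell in 3 (median 3.34, or 2.94 at the bounds, adjusted p = 0.00148, and adjusted p = 0.475 with an estimated correlation). Proliferation rose in 30 of 35 and fell in 0 (median 1.86, adjusted p = 0.0001, and adjusted p = 0.498 with an estimated correlation), BUB1, a mitotic checkpoint kinase, by 2.79. Rises and falls were 18 and 7 of 31 for extracellular matrix (median 1.52, adjusted p = 0.0483, and adjusted p = 0.475 with an estimated correlation), COL6A1 rising by at least 7.60 (1 SK-B1-C1 array saturated) and the proteoglycan VCAN falling by 4.83. This call was lost without SK-B1-C1 replicate 3. They were 15 and 3 of 30 for focal adhesion (median 1.08, adjusted p = 0.0412, and adjusted p = 0.475 with an estimated correlation), the focal adhesion kinase PTK2 rising by 2.82, and 16 and 3 of 30 for interferon-stimulated genes (median 1.48, adjusted p = 0.045, and adjusted p = 0.475 with an estimated correlation). The ribosome held 11 and 0 of 29 (median 0.75, adjusted p = 0.0144, and adjusted p = 0.571 with an estimated correlation) and oxidative phosphorylation 10 and 1 of 28 (median 0.76, adjusted p = 0.00648, and adjusted p = 0.475 with an estimated correlation). Quantile scaling ended the matrix, focal adhesion, interferon, ribosome and oxidative phosphorylation calls, leaving out the SKBR-3 arrays the interferon call, and median centring or the mean of all probes the matrix call. Adjusted over the list alone, only immediate early genes moved (5 rises, 6 falls), and their median (0.14) was above 0 with mean and test below.

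SKBR-3/ b1 against SKBR-3/ EV compared the lines whose labels differ only in b1 and EV. It gave 10221 called genes, 5350 higher and 4871 lower, and 90.4% of genes were non-overlapping (10% by chance). These lines were scanned on different days, so that their differences cannot be told apart from the day. The 7996 called genes above background in both were mostly lower (3290 higher, 4706 lower), as were all called genes under quantile scaling (39.8% higher) and median centring (29.1%). AD7C-NTP rose by 8.77 log2, MOP-1 by 8.55 and ANKDD1A by 8.42, and the linker histone H1-10 fell by 4.28, CSRP2 (-4.16) and IGFBP2 (-4.14). MOP-1 was also among the largest falls of SK-B1-C1 against SK-EV-C4, a line scanned on the same day as SKBR-3/ b1. GSTM2 was at least 239-fold higher and KCNMB2 at least 13.9-fold lower. ERBB2 differed by at most 0.24 (adjusted p = 0.432, SKBR-3/ EV saturated), and its unsaturated probe by -0.93, under 2-fold. Extracellular matrix genes rose in 21 of 31 cases and fell in 3 (median 1.64, or 1.34 at the bounds, adjusted p = 0.00402, and adjusted p = 0.63 with an estimated correlation), COL6A3 by 7.42 and VCAN by 5.66. Mesenchymal genes rose in 15 of 25 and fell in 3 (median 1.99, or 1.28 at the bounds, adjusted p = 0.0177, and adjusted p = 0.63 with an estimated correlation), with the transcription factors SNAI2 up 5.83 and TWIST1 up 3.46. Melanocytic genes rose in 10 of 15 and fell in 1 (median 2.67, or 2.48 at the bounds, adjusted p = 0.0358, and adjusted p = 0.63 with an estimated correlation), MLANA by at least 44.3-fold. Proliferation fell in 28 of 35 and rose in 0 (median -1.45, adjusted p = 0.000778, and adjusted p = 0.721 with an estimated correlation), MCM5 (-2.23). N-glycan genes fell in 17 of 46 and rose in 3 (median -0.58, adjusted p = 0.0489, and adjusted p = 0.721 with an estimated correlation), the mannosyltransferases ALG9 (-2.40) and ALG3 (-2.30), while ST3GAL3 rose by 2.92. The ribosome held 2 rises and 12 falls of 29 (median -0.91, adjusted p = 0.00952, and adjusted p = 0.721 with an estimated correlation), and oxidative phosphorylation 0 and 18 of 28 (median -1.47, adjusted p = 3.57e-05, and adjusted p = 0.63 with an estimated correlation), COX5B falling by 2.97. The N-glycan call was lost without SKBR-3/ EV replicate 2, SKBR-3/ b1 replicate 2 or SKBR-3/ b1 replicate 3, with quantile scaling and with the mean of all probes. Quantile scaling also ended the melanocytic, ribosome and oxidative phosphorylation calls, the mean of all probes the mesenchymal and melanocytic calls, and use of all genes without a filter the melanocytic call. Adjusted over the list alone, only the unfolded protein list moved (1 rise, 9 falls). Median, mean and test differed in sign for luminal (median -0.54, mean 0.30), MAPK (-0.19, 0.08), invasion (-0.06, 0.37) and drug efflux genes (-0.34, 0.08), none called.

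SK-EV-C4 against SKBR-3/ EV, the EV-named pair, scanned on different days, gave 11746 called genes, 6307 higher and 5439 lower. Arrays did not overlap for 93.5% of genes (10% by chance). The 9033 called genes above background in both were mostly lower (4029 higher, 5004 lower), as were all called genes under median centring (34.3% higher). SFRP1, a Wnt antagonist, rose by 10.501 log2, MSN by 10.2 and ITGA6 by 9.72, while BMP7 fell by 11.1, CTAG1A (-9.94) and H19 (-9.34). G0S2 was at least 4352-fold higher, CDH1 at least 909-fold higher and SELENBP1 at least 3692-fold lower. ITGB1 rose by 1.61 (adjusted p = 1.86e-07), a call that median centring ended (0.47), and its other chromosome 10 probes gave only 0.82 and 0.89, under 2-fold. ERBB2 differed by -2.68 or lower, being saturated in SKBR-3/ EV, and its unsaturated probe fell by 3.91. Integrin subunits rose in 17 of 25 cases and fell in 4 (median 2.40, or 1.71 at the bounds, adjusted p = 0.0247, and adjusted p = 0.546 with an estimated correlation), extracellular matrix in 23 of 31 with 4 falls (median 3.37, or 2.79 at the bounds, adjusted p = 0.00195, and adjusted p = 0.539 with an estimated correlation), and mesenchymal genes in 16 of 25 with 5 falls (median 2.75, adjusted p = 0.036, and adjusted p = 0.546 with an estimated correlation). Interferon-stimulated genes rose in 24 of 30 and fell in 2 (median 3.37, or 3.32 at the bounds, adjusted p = 1.63e-05, and adjusted p = 0.539 with an estimated correlation), OASL by 9.18 and HERC6 by 7.07, and NF-kB targets rose in 15 of 27 and fell in 6 (median 1.97, adjusted p = 0.036, and adjusted p = 0.539 with an estimated correlation), IL1B by at least 471-fold. Epithelial genes fell in 14 of 24 and rose in 2 (median -1.78, adjusted p = 0.011, and adjusted p = 0.54 with an estimated correlation), proliferation fell in 19 of 35 and rose in 0 (median -1.03, adjusted p = 0.0225, and adjusted p = 0.725 with an estimated correlation), and the unfolded protein list fell in 12 of 22 and rose in 3 (median -1.70, adjusted p = 0.0414, and adjusted p = 0.67 with an estimated correlation). The ribosome fell in 18 of 29 and rose in 0 (median -1.25, adjusted p = 0.00195, and adjusted p = 0.609 with an estimated correlation), and oxidative phosphorylation fell in 22 of 28 and rose in 0 (median -1.86, adjusted p = 2.95e-06, and adjusted p = 0.539 with an estimated correlation), COX5B (-3.36). Quantile scaling ended the epithelial, mesenchymal, proliferation, unfolded protein and ribosome calls, median centring the unfolded protein call, and normexp correction or leaving out the SKBR-3 arrays the NF-kB call. Median, mean and test differed in sign for focal adhesion (median 0.01, mean 0.25), trastuzumab response (-0.47, 0.47) and drug efflux (-0.43, 0.23), none called.

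SKBR-3/ EV against SKBR-3, the line it is named after, gave 6048 called genes, 1576 higher and 4472 lower, of which 2048 were above background in both lines (700 higher, 1348 lower). Quantile scaling turned the balance (3057 higher, 1964 lower), and a fit of these 2 lines alone called 3075 (1318 higher, 1757 lower). In neither line above background were 1677, all lower, beside the dim SKBR-3 arrays. Arrays did not overlap for 57.4% of genes (10% by chance). PRDX3, a mitochondrial peroxidase, rose by 3.03 log2, CAPZA2 by 2.74 and FAM83D by 2.71, and CD86 fell by 7.03, the kinase HIPK2 (-6.65) and LCN2 (-6.49). SERPINE1 was at least 8.50-fold higher and GLYATL1 at least 58.9-fold lower. ITGB1 differed by -0.40 and was not called, its other chromosome 10 probes giving -0.24 and 1.17, and the ERBB2 difference was -2.85 log2 or higher, since SKBR-3/ EV was saturated, so that its call is not a measured fall. The unsaturated ERBB2 probe differed by 0.09 (adjusted p = 0.828). Quantile scaling ended that call (-0.71). Interferon-stimulated genes fell in 20 of 30 cases and rose in 1 (median -1.85, adjusted p = 3e-05, and adjusted p = 0.474 with an estimated correlation), BST2 (-3.03) and IFI6 (-2.85). Proliferation rose in 18 of 35 and fell in 0 (median 1.11, or 0.93 at the bounds, adjusted p = 1.21e-05, and adjusted p = 0.802 with an estimated correlation), the kinase CDK1 by 1.70. Heat shock genes rose in 6 of 16 and fell in 0 (median 0.62, or 0.41 at the bounds, adjusted p = 0.0106, and adjusted p = 0.474 with an estimated correlation), and focal adhesion genes in 7 of 30 with 0 falls (median 0.20, or 0.14 at the bounds, adjusted p = 0.0152, and adjusted p = 0.474 with an estimated correlation). The focal adhesion call was lost without SKBR-3 replicate 3 and with quantile scaling. The ribosome fell in 15 of 29 and rose in 0 (median -1.03, adjusted p = 3e-05, and adjusted p = 0.777 with an estimated correlation), but the direction of its test reversed with quantile scaling (0.17) and with normexp correction (-0.005). Median, mean and test differed in sign for trastuzumab response (median 0.08, mean -0.14), immediate early (-0.35, -0.22, test up), hypoxia (-0.01, -0.21, test up), sterol (0.02, -0.08) and drug efflux genes (-0.25, -0.24, test up), none called.

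The other 5 lines against SKBR-3 gave 10499 called genes for MDA-MB-231 (3290 higher, 7209 lower, 3987 above background in both lines), 10787 for MDA-MB-435 (3531, 7256, 3974), 10351 for MDA-MB-468 (3169, 7182, 4018), 9902 for MCF-7 (3112, 6790, 3909) and 9600 for ZR75-1 (3178, 6422, 3794). Above background in neither line were 1780 (MDA-MB-231), 2097, 1799, 2062 and 2168 (ZR75-1) of these, beside the dim SKBR-3 arrays. With quantile scaling the higher genes were the majority in all 5 lines (53.6% to 56.2%). In at least 1 of them 15721 of 17696 genes were called. TFF1, an estrogen-induced peptide, was at 6.68 in MCF-7 and 4.69 in ZR75-1, FOXA1 at 4.87 and 3.90, and CDH1 at 5.24 and 5.69. MDA-MB-468 held KRT5 at 3.90 and EGFR at 3.38. VIM stood at 6.48 in MDA-MB-231 and 6.42 in MDA-MB-435, where it was saturated, and AXL at 5.58 in MDA-MB-231. MDA-MB-435 had S100B at 4.102, TYR, tyrosinase, at 4.32 and HLA-DRA at 4.17, with CDH1 above background on no array.

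The design text followed genes that differed between SK-B1-C1 and SKBR-3/ EV into the other lines. Over the 7059 genes called here, the change between those lines correlated with that of MDA-MB-231 against SKBR-3 at r = 0.606 (rho 0.586, 80.0% with the same sign), MDA-MB-435 at 0.607 (rho 0.570, 78.0%), MDA-MB-468 at 0.289 (rho 0.298, 69.7%), MCF-7 at 0.284 (rho 0.269, 66.1%) and ZR75-1 at 0.291 (rho 0.271, 66.4%). Genes are not independent replicates, and both sides subtract a line derived from SKBR-3, so that some positive correlation is built in. No value of r in the absence of a shared change was available. All genes gave 0.515, 0.522, 0.233, 0.230 and 0.230, and 1000 random lists of the same size lay between 0.481 and 0.551 for MDA-MB-231, 0.484 and 0.559 for MDA-MB-435, 0.190 and 0.271 for MDA-MB-468, 0.190 and 0.270 for MCF-7, and 0.185 and 0.268 for ZR75-1. Genes called for a large change spread more widely than random ones, which raises r by itself, so these lists are no test of a shared change.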

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

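The tests of the 3 patterns weighed here were chosen after their results were seen, while the counts over other splits of the arrays were planned. Groups of 3 arrays are too small for a test of single outlying arrays.

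The change between SK-B1-C1 and SKBR-3/ EV differed from that between SKBR-3/ b1 and SK-EV-C4 for 9077 genes, by a test of the difference itself. For ITGB1, on its brightest probe, the difference of the changes was 3.23 log2, and for ERBB2 it was -8.26 or lower, because SKBR-3/ EV was saturated. Of 100 splits of the 12 arrays, 1, the real one, gave as many genes (highest other 7884). Such splits break up lines whose replicates are alike, so they cannot test how whole lines were grouped. Pairing whole lines by scan day in the same contrast gave more, 13629 genes. The contrast of 9077 genes also sets the lines with a C suffix, SK-B1-C1 and SK-EV-C4, against SKBR-3/ EV and SKBR-3/ b1. Whether its genes follow that suffix rather than the b1 and EV names cannot be told from these lines.

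ERBB2 was lower and VIM higher in the SK-B1-C1 arrays than in the SKBR-3/ EV arrays. A slide difference as the whole cause is argued against by the 1 slide that held both lines, where ERBB2 still differed by -5.36 log2 or lower. Arrays of another measured line under this label are argued against too, since no SK-B1-C1 array correlated with an array of the 5 other lines above 0.872, while the lowest correlation between replicates of a line was 0.934. A line unrelated to SKBR-3 stays open: the SK-B1-C1 and SKBR-3/ EV means correlated at 0.825 across genes, inside the 0.801 to 0.901 of pairs of unlike lines, and SKBR-3/ EV and SKBR-3 at 0.940. SK-B1-C1 correlated at 0.794 with SKBR-3, whose arrays were dim. With each of the 5 other lines it correlated more highly, from 0.8095 (ZR75-1) to 0.879 (MDA-MB-231). A change of state in cells derived from SKBR-3, which the labels name, may account for the pattern as well and was not tested apart from this.

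ITGB1 was lower in the SKBR-3/ b1 arrays than in the SK-EV-C4 arrays, against the order of their names. Swapped labels of these lines could account for this and stay open. With the labels exchanged, the r = -0.481 across genes given above turns to 0.481, so it is no separate test of a swap. A difference along the C suffix of SK-B1-C1 and SK-EV-C4 would give the same r and cannot be told apart from a swap here. A mixture of SKBR-3/ b1 and SK-B1-C1 RNA in the SK-EV-C4 arrays is argued against by CDH1, above background on all SK-EV-C4 arrays and on no array of SKBR-3/ b1, SKBR-3/ EV or SK-B1-C1, and at least 9.15 log2 over the highest of their bounds. The number of such genes, 94 (0.549%), does not by itself go against a mixture. A line unrelated to SKBR-3 under the SK-EV-C4 label was not tested and stays open as well. SK-EV-C4 correlated across genes at 0.742 with SKBR-3/ EV and 0.714 with SKBR-3, both scanned on another day. Pairs of unlike lines gave 0.801 to 0.901, and SK-EV-C4 with SKBR-3/ b1, of the same day, gave 0.876. A real difference between SKBR-3/ b1 and SK-EV-C4 remains open and was not tested, and ITGB1 protein was not measured.

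More genes were called between lines scanned on different days, with different Feature Extraction releases, than between lines scanned on the same day (10221 to 11746 against 4636 to 7059). The changes from one scan day to the other in the 2 line pairs correlated at r = 0.671, and 91.3% of the 8358 genes called in both went the same way, which is consistent with an effect of scan day or release. The 10 control spikes, which come from no line, also shifted unevenly between the days, with an SD over spikes of 0.617 to 0.868 log2 between lines of different days and 0.241 and 0.250 between lines of the same day, so part of the difference between days is technical. How much of each gene's or list's change is technical stays open, since the pairs also differ as lines and each line was scanned on 1 day. On the SKBR-3/ b1 and SK-EV-C4 arrays the 75th percentile was 5.33 to 5.66 times the median signal, against 8.87 to 13.2 on the other arrays.

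For 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. SK-B1-C1 against SKBR-3/ EV had 7059 genes (highest other 1), SKBR-3/ b1 against SKBR-3/ EV 10221 (0), SK-B1-C1 against SK-EV-C4 11440 (0), SKBR-3/ b1 against SK-EV-C4 4636 (0), SK-B1-C1 against SKBR-3/ b1 11740 (0), SK-EV-C4 against SKBR-3/ EV 11746 (0) and SKBR-3/ EV against SKBR-3 6048 (28). Against SKBR-3, MDA-MB-231 had 10499 (2905), MDA-MB-435 10787 (411), MDA-MB-468 10351 (1031), MCF-7 9902 (1305) and ZR75-1 9600 (97). Of 100 splits, 1, the real one, gave as many genes among the 3 lines (13779, highest other 11054). The same held for genes changed the same way in all 4 pairings (122, highest other 68). Such splits break up lines whose replicates are alike, so they do not exclude that whole lines were grouped by chance. Pairing the lines by scan day gave 6132 genes and the remaining pairing 1585 in place of the 122, which points to a structure of the samples other than the b1 and EV names.

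A signal also lay outside the gene tables. Of 9331 probes without a gene name, 3472 were called between SK-B1-C1 and SKBR-3/ EV, 1034 higher and 2438 lower. The 6 columns of the deposited table labelled MDA-MB-231 and MCF-7 matched no scanner file.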

How the results depend on the processing

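Slide as a block for gene lists, the mean of the ITGB1 probes on chromosome 10, the fits without the SKBR-3 arrays and SKBR-3/ EV in place of SKBR-3 as the reference were chosen after seeing the data; the other alternatives were planned. Direction was compared only for results called in the main fit, so changes of sign among uncalled ones are not counted as reversed. Of 31027 values of named genes under the alternatives, 30033 kept a call and its direction or stayed uncalled. Another 565 lost the call, 308 gained it and 121 reversed. Of 3180 list values, 2888 kept a call and its direction or stayed uncalled, 104 lost the call, 186 gained it and 2 reversed. Signal over background limits what the SKBR-3 comparisons can show, since at most 55.0% of probes were well above background on those arrays. Scan day could not be fitted as a term beside the lines. Array weights were lowest for SKBR-3 (0.0372 to 0.236).

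The number of genes called between SK-B1-C1 and SKBR-3/ EV stayed within 1.5 times 7059 under 16 of 18 alternatives, between 4721 (normexp) and 10519 (no fold minimum), and that between SKBR-3/ b1 and SK-EV-C4 (4636) under 13 of 16, between 4031 (slide as a fixed block) and 6761 (at least 1.5-fold). ITGB1 kept its rise of SK-B1-C1 over SKBR-3/ EV under all 20 alternatives other than single arrays left out (1.27 to 1.63, highest from the probe placed on chromosome 8). A replicate block treats arrays of one number as a pair. With it, counts were 6965, 4602, 10197, 11423, 11730, 11714 and 5994, in the order of comparisons of the next paragraph, and 8984 for the difference of the changes. With SKBR-3/ EV as the reference line, the other lines gave 8496 (MDA-MB-231), 8133 (MDA-MB-435), 7990 (MDA-MB-468), 7822 (MCF-7) and 7778 (ZR75-1).

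The stricter filter tests fewer genes, so its counts fell: 2581 for SK-B1-C1 against SKBR-3/ EV, 2236 for SKBR-3/ b1 against SK-EV-C4, 4401 for SKBR-3/ b1 against SKBR-3/ EV, 4766 for SK-B1-C1 against SK-EV-C4, 4725 for SK-B1-C1 against SKBR-3/ b1, 5127 for SK-EV-C4 against SKBR-3/ EV, 1867 for SKBR-3/ EV against SKBR-3, 4439 for the difference of the changes, 6189 among the 3 lines, 38 in all 4 pairings, and against SKBR-3 3666 for MDA-MB-231, 3763 for MDA-MB-435, 3671 for MDA-MB-468, 3549 for MCF-7, 3457 for ZR75-1 and 6787 in any of these. Without a fold minimum, which only adds genes, SKBR-3/ EV against SKBR-3 had 10095, SKBR-3/ b1 against SK-EV-C4 7963 and all 4 pairings 301, and at least 1.5-fold gave 212 in all 4 pairings. Normexp correction gave 9370 for SKBR-3/ EV against SKBR-3, 2940 for SKBR-3/ b1 against SK-EV-C4, 2408 for ZR75-1 and 47 in all 4 pairings, fitting only the compared groups gave 3075 for SKBR-3/ EV against SKBR-3, and the cause was not tested. The t-test with Bonferroni correction, at 0.02 and 1.5-fold, called 1375 genes between SK-B1-C1 and SKBR-3/ EV, 1339 of them also called by limma. The plain ANOVA called 13842 genes among the 3 lines, near limma's 13779.

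With an estimated correlation 0 lists were called in each of the 7 comparisons, where the preset correlation gave 5 to 11. The fry test asks whether a list's genes move one way rather than whether they move more than others. It called 25, 20, 23, 29, 28, 27 and 24 lists, in the order of comparisons of the previous paragraph. Quantile scaling left 4 lists for SK-B1-C1 against SKBR-3/ b1, 5 for SK-EV-C4 against SKBR-3/ EV and 3 for SKBR-3/ b1 against SKBR-3/ EV. Normexp correction called 10 for SKBR-3/ EV against SKBR-3 and 14 for SKBR-3/ b1 against SK-EV-C4, the mean of all probes 4 for SKBR-3/ b1 against SKBR-3/ EV, and the cause was not tested.

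ITGB1 in SKBR-3/ b1 against SK-EV-C4 missed the call with the mean of all probes (-0.96) and with either other probe on chromosome 10 (-0.49 and -0.68), since other probes then give the value. The mean of all probes takes in one that the files name ITGB1 and place on chromosome 8 (-0.73 alone), which is no evidence on ITGB1, and without it the mean kept the call (-1.035). Correlations of the genes called between SK-B1-C1 and SKBR-3/ EV with the other lines moved beyond the spread between replicates as follows, and the cause was not tested. MDA-MB-231 went from 0.606 to 0.515 with all genes, 0.591 with the mean of all probes, 0.567 with normexp and 0.647 with quantile scaling; MDA-MB-435 from 0.607 to 0.522, 0.594, 0.598 and 0.646, and 0.593 at 1.5-fold. MDA-MB-468 went from 0.289 to 0.233, 0.266, 0.240 and 0.375, 0.284 at 1.5-fold and 0.278 without a filter, MCF-7 from 0.284 to 0.230, 0.260, 0.194 and 0.364, and 0.323 with the deposited table. ZR75-1 went from 0.291 to 0.230 with all genes, 0.260 with the mean of all probes and 0.358 with quantile scaling. Leaving out 1 array gave 0.568 to 0.627 for MDA-MB-231, 0.573 to 0.624 for MDA-MB-435, 0.241 to 0.326 for MDA-MB-468, 0.235 to 0.320 for MCF-7 and 0.236 to 0.333 for ZR75-1, lowest without SKBR-3 replicate 1 and highest without SKBR-3 replicate 3.

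Scaling moved the share of called genes that were higher by over 10 points in some comparisons. SKBR-3/ b1 against SKBR-3/ EV went from 52.3% to 39.8% with quantile scaling and 29.1% with median centring. Median centring took SK-B1-C1 against SK-EV-C4 from 44.9% to 65.1%, SK-B1-C1 against SKBR-3/ b1 from 45.4% to 64.1% and SK-EV-C4 against SKBR-3/ EV from 53.7% to 34.3%. SKBR-3/ EV against SKBR-3 went from 26.1% to 60.9% with quantile scaling and 15.8% with normexp. Against SKBR-3, quantile scaling took MDA-MB-231 from 31.3% to 53.6%, MDA-MB-435 from 32.7% to 55.5%, MDA-MB-468 from 30.6% to 56.2%, MCF-7 from 31.4% to 53.6% and ZR75-1 from 33.1% to 55.2%, and normexp took the first 4 to 17.6%, 20.9%, 18.1% and 16.2%. Genes changed in all 4 pairings went from 41.8% to 16.7% with median centring and 23.2% with quantile scaling. The median change of all genes moved by over 0.1 log2 with median centring for SKBR-3/ b1 against SKBR-3/ EV (by -1.09), SK-B1-C1 against SK-EV-C4 (1.23), SK-B1-C1 against SKBR-3/ b1 (1.18), SK-EV-C4 against SKBR-3/ EV (-1.14) and SKBR-3/ EV against SKBR-3 (0.15), and for MDA-MB-231 (-0.14), MCF-7 (-0.23) and ZR75-1 (-0.21). Quantile scaling moved the first 5 of these by -0.21, 0.26, 0.29, -0.20 and 0.48, SK-B1-C1 against SKBR-3/ EV by 0.14, and the other lines by 0.57 to 0.75. Normexp moved the same 5 by 0.29, -0.33, -0.18, 0.43 and -0.44, SK-B1-C1 against SKBR-3/ EV by 0.18, SKBR-3/ b1 against SK-EV-C4 by -0.28, and MDA-MB-231, MDA-MB-435, MDA-MB-468 and MCF-7 by -0.28, -0.20, -0.23 and -0.31. The deposited table moved MCF-7 by 0.15.

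The ribosome list of SKBR-3/ EV against SKBR-3 reversed its direction of test with normexp (-0.005) and quantile scaling (0.17), and the cause was not tested. The model-based background correction (normexp) turned 58 of the named-gene differences, given as log2 values in the direction written. The cause was not tested. For SKBR-3/ b1 against SK-EV-C4 they were ALDH1A1 (-0.39), F2R (-0.47) and MMP2 (-0.54). Those of SKBR-3/ EV over SKBR-3 were CAV2 (-1.204), HSPA4L (-0.048), HSPB8 (-0.99), JAG1 (-1.09), MSMO1 (-0.30), RRM2B (-0.80) and SPRED1 (-1.40). Between MCF-7 and SKBR-3 the values were CCNE2 (-0.41), FAS (-0.45), ITGA6 (-1.01), MAN1A1 (-0.58), NEDD9 (-0.44), PHLDA1 (-0.35), PLAT (-0.94) and SERPINE2 (-1.04). In MDA-MB-231 relative to SKBR-3 they were CCNE2 (-1.18), CDH1 (-0.39), CDH3 (-0.98), FAS (-0.98), HSPB8 (-1.103), ITGB3 (-0.64), LAPTM5 (-0.65), LPXN (-0.12), PDGFRB (-1.39), RAB38 (-0.84) and ST3GAL6 (-0.22). The MDA-MB-435 against SKBR-3 values were CCNE2 (-0.43), FAS (-0.68), HSPB8 (-0.16), IFIT3 (-0.16) and SLC7A11 (-0.40). The list for MDA-MB-468 less SKBR-3 held CCNE2 (-0.43), ERAP2 (-0.24), ETV5 (-0.85), FAP (-0.43), FAS (-1.37), HSPA1L (-1.001), IFIT3 (-0.18), SERPINE2 (-0.98), SLC7A11 (-0.27), ST3GAL6 (-0.85) and TNC (-0.86). For ZR75-1 against SKBR-3 they were CCNE2 (-0.076), FAS (-0.25), HSPA1L (-0.37), MAN1A1 (-0.45), NRG1 (-0.045), PARVB (-0.10), PHLDA1 (-0.13), PROM1 (-0.47), ST3GAL6 (-0.58) and TNC (-0.23). Those of SKBR-3/ b1 over SKBR-3/ EV were CUZD1 (0.37) and CXCL11 (0.66). Between SK-B1-C1 and SK-EV-C4 it was SPRY1 (-1.16).

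Quantile normalization turned 38, and the cause was not tested. For SKBR-3/ EV against SKBR-3 they were ABCC4 (0.17), PDGFRB (0.98), RPS6 (0.51) and TRIB3 (0.097). Those of SKBR-3/ b1 over SKBR-3/ EV were ABCC4 (-0.17), COL1A1 (-0.31) and ETV4 (-0.005). Between MCF-7 and SKBR-3 the values were CD2 (0.76), LAPTM5 (2.27), MMP3 (0.40), PDGFRB (0.21), SPARC (0.98), TWIST2 (0.49) and TYR (1.10). In MDA-MB-435 relative to SKBR-3 they were CD2 (0.84), CDH11 (0.48), EGR3 (0.89), LAPTM5 (2.30), PDGFRB (0.89) and RPS27 (0.12). The MDA-MB-468 against SKBR-3 values were CD2 (0.46), CDH11 (0.36), LAPTM5 (0.88), RPS27 (0.078), SPARC (1.11) and TYR (1.09). The list for ZR75-1 less SKBR-3 held CD2 (0.59), LAPTM5 (0.72), RPS2 (0.014), RPS27 (0.35), SPARC (0.26) and TYR (0.78). For MDA-MB-231 against SKBR-3 they were MAN1A1 (0.44), MMP3 (0.10), PARVB (0.12), PLP1 (0.26), TWIST2 (0.46) and TYR (1.85).

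The deposited value table turned 15, all in the MDA-MB-231 or MCF-7 columns, which match no scanner file, and the cause was not tested. For MDA-MB-231 against SKBR-3 they were ABCC3 (-1.76), CA9 (-0.58), CDH1 (-1.75), CDKN1A (-0.47), COL1A2 (-3.93), MAN1A1 (0.82), NEDD9 (-4.78) and SAA1 (-4.50). Those of MCF-7 over SKBR-3 were GSTM1 (0.29), HLA-DMB (0.68), IFI44 (1.47), PARVB (0.88), RSAD2 (2.43), SCD (-0.66) and VIM (3.92).

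The mean of all probes of a gene turned 7, because other probes of the gene then enter the value. These were CAV2 (-0.97) in SKBR-3/ EV over SKBR-3, MDM2 (0.096) in SKBR-3/ b1 over SKBR-3/ EV, MGAT5B (-0.022) in MDA-MB-231 over SKBR-3, MYC (0.83) in SK-EV-C4 over SKBR-3/ EV, PTGER3 (-0.071) and VEGFA (-0.90) in SK-B1-C1 over SK-EV-C4, and VEGFA (-0.83) in SK-B1-C1 over SKBR-3/ b1.

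Centring on the array median turned 2 values, and the cause was not tested. These were EGFR (-0.065) in SKBR-3/ b1 over SKBR-3/ EV and JUNB (0.15) in SK-B1-C1 over SK-EV-C4.

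The stricter filter turned 1, because the gene is then read from another probe. It was CLDN3 (0.16) in SKBR-3/ b1 over SKBR-3/ EV.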

Other observations

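Single genes outside the groups called in SK-B1-C1 against SKBR-3/ EV moved far. The transporter ABCC3 rose by 3.18 log2 and ABCC5 fell by 3.18. Among p53 targets the death receptors FAS and TNFRSF10B rose by 4.76 and 2.32, and the kinase PLK3 fell by 2.23. The cystine transporter SLC7A11 rose by 4.56, the unfolded protein regulator XBP1 fell by 2.14, and the hypoxia genes ADM and ALDOC changed by 3.78 and -5.69. MET, a receptor kinase, rose by 2.15, PHLDA1 by 7.27 and the cytokine IL6 by 5.56, whereas KLF4 fell by 3.42 and IER3 (-8.57).

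In SKBR-3/ b1 against SK-EV-C4 the immediate early genes FOS and ATF3 rose by 3.98 and 3.28 and FOSL1 fell by 3.65. PLAT, tissue plasminogen activator, was at least 204-fold lower, the cathepsin CTSB fell by 2.77, and the inhibitor TIMP2 rose by 2.97. The small heat shock genes HSPB1 and HSPB8 changed by 3.64 and -2.86. AXL fell by 3.90 while S100A4 and FBN1 rose by 4.79 and 3.61, and of the focal adhesion genes FERMT1 fell by 4.56, PXN (-1.85) and PTK2 (-1.50) while ILK rose by 1.85. GADD45A fell by 2.94.

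Among the other lines, AGR2 stood at 5.36 in MCF-7 and 4.72 in ZR75-1, KRT23 at 4.53 in MDA-MB-468, GSTP1 at 6.27 in MDA-MB-231, and PLP1, RAB38 and CD74 at 3.27, 1.83 and 3.11 in MDA-MB-435. The SK-B1-C1 line mean correlated across genes at 0.879 with MDA-MB-231, 0.877 with MDA-MB-435, 0.718 with SK-EV-C4 and 0.676 with SKBR-3/ b1.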
